A study of Mus musculus with 10 samples.

How the data were processed

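Gene expression was measured in haematopoietic stem cell-enriched bone marrow cells from 10 mice, with 1 array for each mouse. Per the labels' protocols, 5 mice carried Mll alleles flanked by loxP sites together with the interferon-inducible Mx1-cre transgene, and 5 control mice carried the floxed alleles without cre. All were females aged 8 weeks on a B6.SJL background. Both groups received 3 injections of polyinosinic:polycytidylic acid, a double-stranded RNA mimic that raises interferon and so switches Mx1-cre on, at 10 µg per gram of body weight plus 50 µg, every 48 hours. Bone marrow was taken on day 6 and sorted for LSK/CD48- cells, the lineage-negative, Sca-1-positive, Kit-positive fraction that lacks CD48. Total RNA from 1500 to 10000 sorted cells was amplified, labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 sample per array.

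The deposited values are linear signal intensities per probe set, made with MAS5 5.0 per the submitters' processing notes. They were not on a log scale and not centred per gene. On each of the 10 arrays the mean of the deposited intensities, after dropping the lowest and highest 2% of probe sets, was 150.001, so each array had been scaled to 1 constant. No detection calls were used here, and scanner files were not analysed here. Such scaling removes any difference in total RNA per cell, and the amplification of small amounts of RNA favours the 3' ends of transcripts. For arrays, the number of arrays limits the precision.

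The table held 45101 probe sets, of which 64 were control probe sets. A platform annotation table paired 34958 probe sets with 1 gene symbol and 932 with several, and 9211 were unnamed here. Symbols were updated through Entrez identifiers and the RefSeq gene table of the GRCm38.p6 assembly, in which 34754 of the probe sets with 1 symbol were found and 204 were not. No probe set with several symbols was used to name a gene, and no coordinates were taken. Values were transformed as log2(signal + 16). This offset understates fold changes of dim genes. Each of 18193 genes was represented by its probe set with the highest mean over all 10 arrays, and the 12580 genes with a mean above the 40th percentile of all probe sets were tested. Differences are given as Mll-deficient minus control on this log2 scale, with the standard error (SE) of the model.

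The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Each adjusted p for a gene comes from this limma fit. Gene lists were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists that had at least 3 tested members. The same test with an estimated correlation and limma's fry were run beside it. For each list, the mean log2 value of its members on each array was also compared between the groups by a two-sided exact permutation test over all 252 assignments, whose smallest possible p was 0.00794. The Y-linked list had 0 tested members. A list of regulators recalled from the published study of these arrays was included and is not independent of these samples.

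The genes named in the text were Kmt2a, which encodes Mll, the 12 genes with the largest rises and the 12 with the largest falls among those past the threshold, the recalled regulators, up to 4 genes with the smallest p from each list, and a fixed set of stem cell and lineage genes. Some genes of these sets are not reported here. A name outside this rule is stated to have been chosen after its values were seen. The log2 ratio of the 3' to the middle probe sets of Gapdh and Actb, averaged, served as a measure of RNA quality.

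The procedure was tested on simulated data made from the real means and spreads of the 12580 genes, with 200 genes changed. For this comparison it recovered 0 of 50 genes changed by 0.5 on the log2 scale, 16 of 50 changed by 1, 49 of 50 changed by 2 and 50 of 50 changed by 3. Of 121 genes called, 6 were unchanged ones. The simulated genes varied independently, unlike real ones. Alternatives covered the offset (1 and 64), quantile normalization, centring on each array's median, the filter (none, and the 60th percentile), the mean of all probe sets of a gene, the variance prior, array weights, a replicate block, other thresholds and leaving out each array in turn. The mean of all probe sets took in those below the filter. No pairing of the arrays by replicate number was seen. A fit with the RNA quality measure as a covariate was added after the data had been seen.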

Results

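The series asked which genes depend on Mll (gene symbol Kmt2a), a histone H3 lysine 4 methyltransferase, in adult haematopoietic stem cells. RNA of sorted LSK/CD48- bone marrow cells, a fraction enriched for stem cells, was compared between 5 Mll-deficient mice and 5 control mice, each on 1 array. All 10 arrays had the same scaled mean signal, and their median signal lay between 18.1 and 28.9 arbitrary units. Correlations between arrays over the tested genes ranged from 0.896 to 0.969. Control replicate 5 stood apart, with a mean correlation of 0.926 with the other controls and the highest 3' to middle ratio, at 5.24 on the log2 scale. This ratio averaged 2.97 ± 1.42 (SD, n = 5) in controls and 3.16 ± 0.60 (SD, n = 5) in Mll-deficient samples, a difference smaller than the spread between arrays (exact permutation p = 0.810). Control mice lacked cre, so the effects of cre and of Mll loss were not separated by the design.

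The targeted gene had 2 probe sets with a single symbol, and neither passed the test, in a fit over all probe sets with no filter. The brighter one, 1427283_at, had a signal of 260 ± 85.8 (SD, n = 5) in controls and 216 ± 97.2 (SD, n = 5) in Mll-deficient samples, a log2 difference of -0.38 ± 0.35 (SE, adjusted p = 0.736). The dimmer one, 1452377_at, had 74.7 ± 22.1 and 49.7 ± 32.0, a difference of -0.55 ± 0.31 (SE, adjusted p = 0.498). The unadjusted p of both lay above 0.05, at 0.304 and 0.0922. Where these probe sets lie relative to the deleted part of the gene was not analysed here, so they do not check the labels. Without Mll-deficient replicate 4, where the brighter probe set read 52.2, its difference was 0.02.

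Among the genes that passed the test, the erythroid regulators Klf1 and Gata1, the metallothionein genes Mt1 and Mt2 and the replication gene Mcm2 were higher in Mll-deficient cells, and the transcription factor genes Mecom, Prdm16 and Hoxa9 and the interferon-induced gene Rsad2 were lower. Of 12580 tested genes, 694 passed an adjusted p of 0.05, of which 473 were higher and 221 lower in Mll-deficient cells. At least 2-fold differences were seen for 280 of the higher and 122 of the lower genes. The arrays of the groups did not overlap for 538 of the 694 genes, and for 6.96% of all tested genes, where chance gives 0.794%. Among all 27022 tested probe sets, 887 passed, 573 of them higher and 314 lower. The count of genes depended on single arrays: it was 365, 391 and 374 without control replicates 1, 3 and 4, and 455, 364 and 317 without Mll-deficient replicates 1, 3 and 5. Without control replicate 5 it was 875. Of 23 gene lists, 12 passed camera at the preset correlation, 5 higher and 7 lower, while 0 passed with an estimated correlation, where the smallest adjusted p was 0.0521. Of 100 splits of the arrays into groups of 5, 15 gave as many lists, and chance was not excluded for that count. The exact permutation test of the array means passed for 7 of the 12 lists (the recalled regulators, Hox and cofactors, erythroid, S phase, quiescence, ribosomal proteins and the respiratory chain), each with an adjusted p of 0.0261, and for stroma and endothelium (lower, adjusted p = 0.0456). The limma fry test passed for the same 8 lists and for interferon-induced genes (adjusted p = 0.0192).

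**Figure D1:**
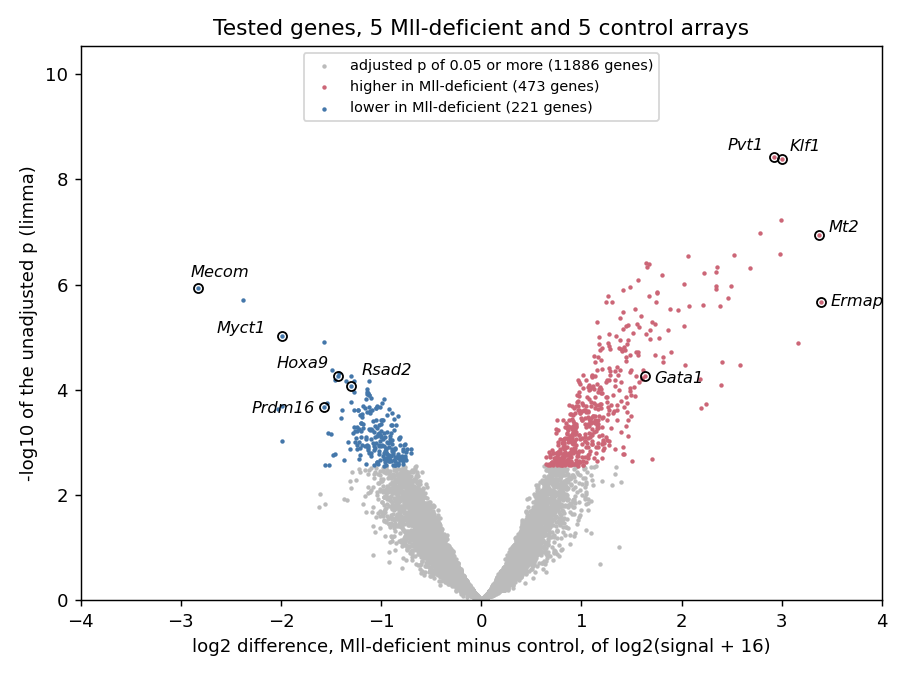
Each point is 1 of the 12580 tested genes, with the log2 difference between Mll-deficient and control arrays (x axis) against -log10 of the unadjusted limma p (y axis). The 473 genes higher and 221 lower in Mll-deficient cells at an adjusted p under 0.05 are coloured, and 10 named genes are circled, with Ermap at 3.40 and Mecom at -2.83.

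Genes linked to stem cells, including those of transcription factors, were among the largest falls. Mecom, a zinc finger factor needed for stem cell maintenance, fell from 461 ± 208 to 57.9 ± 51.1 (SD, n = 5 each), a log2 difference of -2.83 ± 0.38 (SE, adjusted p = 6.58e-04). The size of this fall depended on the processing, and Mecom had no other tested probe set. Over the alternatives that kept all arrays it lay between -3.27 and -0.93, with a highest adjusted p of 0.0101. Myct1 fell by 1.99 ± 0.32 (adjusted p = 0.00204), and Prdm16, a relative of Mecom, by 1.57 ± 0.33 (adjusted p = 0.0127). Hlf, a factor restricted to primitive cells, fell by 1.48 ± 0.40 (adjusted p = 0.0384). Eya1, a transcriptional coactivator, fell by 1.20 ± 0.29 (adjusted p = 0.0257). Of 32 tested genes enriched in long-term stem cells, 5 fell, 2 rose and 25 did not pass, and adjusted over the list alone 14 fell and 2 rose. The rises were Thy1, a surface glycoprotein (1.38 ± 0.27, adjusted p = 0.00816), and Gfi1b, a repressor that also acts in erythroid and megakaryocytic cells (1.46 ± 0.35, adjusted p = 0.0251). The surface markers Procr (-1.08 ± 0.35, adjusted p = 0.0863) and Slamf1 (-0.66 ± 0.25, adjusted p = 0.139) did not pass. As a group the list lay lower than other genes (camera adjusted p = 1.41e-06), with a median of -0.65, but the adjusted p was 0.295 with an estimated correlation. The exact permutation p of its array means was 0.0397 (0.0761 after adjustment over lists). Other probe sets of Prdm16 differed by between -0.51 and 0.10 and did not pass, that of Eya1 was at -0.39 (adjusted p = 0.477), and those of Myct1 were at -1.04 (adjusted p = 0.0360) and -0.76 (adjusted p = 0.104). Averaging the probe sets ended the calls of Prdm16 (-0.49, adjusted p = 0.101) and Eya1 (-0.49, adjusted p = 0.192), and having no filter ended that of Hlf (adjusted p = 0.0579). The calls of Hlf, Eya1 and Gfi1b were lost in 7, 5 and 4 of the 10 fits that left out 1 array.

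Among Hox genes, Hoxa9, a homeodomain factor of stem and progenitor cells, fell from 3522 ± 930 to 1325 ± 452 (SD, n = 5 each), a difference of -1.43 ± 0.27 (SE, adjusted p = 0.00589). Hoxb3 fell by 1.19 ± 0.26 (adjusted p = 0.0143), Hoxa5 by 0.999 ± 0.24 (adjusted p = 0.0216) and Hoxa10 by 1.04 ± 0.29 (adjusted p = 0.0478). Of 17 tested Hox genes and Meis or Pbx cofactors, 4 fell and 13 did not pass, and adjusted over the list alone 8 fell. The cofactor Meis1 (-1.13 ± 0.38, adjusted p = 0.0978) and Hoxa7 (-0.54 ± 0.33, adjusted p = 0.387) were among those that did not pass, although another probe set of Meis1 fell by 1.39 ± 0.34 (adjusted p = 0.0326) and a further one, at -0.55, did not pass (adjusted p = 0.371). The other probe sets of Hoxa9 and Hoxa5, at -0.62 and -0.42, did not pass (adjusted p = 0.198 and 0.378). The list lay lower than other genes (camera adjusted p = 7.48e-06), with an adjusted p of 0.0521 with an estimated correlation. Its array means did not overlap between the groups (exact permutation p = 0.00794, the smallest possible, and 0.0261 adjusted). The call of Hoxa10 was lost in 8 of 10 fits that left out 1 array and in 5 alternatives that kept all arrays (offset 1, quantile normalization, no filter, averaged probe sets and the replicate block, adjusted p between 0.0527 and 0.205), and that of Hoxa5 in 4 of the 10 fits. Averaging the probe sets also ended the call of Hoxb3 (-0.47, adjusted p = 0.104). Of the regulators recalled from the study, all 4 tested (Mecom, Prdm16, Eya1 and Hoxa9) fell, over all genes and adjusted over the list alone (camera adjusted p = 1.68e-06, adjusted p = 0.0661 with an estimated correlation). That list was chosen on these samples and is not independent evidence of its direction.

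Other stem and progenitor regulators went both ways. Of 30 tested, 4 fell, 2 rose and 24 did not pass, and adjusted over the list alone 9 fell and 3 rose. Egr1, an immediate early factor linked to stem cell quiescence, fell by 1.46 ± 0.27 (adjusted p = 0.00654), and Ikzf2, a zinc finger factor, by 0.99 ± 0.22 (adjusted p = 0.0168). Hlf and Gfi1b, given above, also belong to this list. Dnmt3a and Myc, chosen after their values were seen, changed by -0.92 ± 0.25 and 0.79 ± 0.22 (adjusted p = 0.0389 and 0.0455). The list median was -0.36 (camera adjusted p = 0.00408, and adjusted p = 0.295 with an estimated correlation), and the call ended when all probe sets of a gene were averaged (adjusted p = 0.0711). Of 23 genes linked to quiescence, 3 fell and 20 did not pass, and adjusted over the list alone 7 fell. Tob1, an antiproliferative gene, fell by 1.10 ± 0.27 (adjusted p = 0.0264), besides Egr1 and the noncoding RNA Meg3 (-1.99 ± 0.42, adjusted p = 0.0125). Other probe sets of Meg3 differed by between -0.69 and 0.32, and averaging the probe sets ended the calls of Meg3 (-0.28, adjusted p = 0.323) and Tob1 (-0.60, adjusted p = 0.0800), while the call of Tob1 was lost in 6 of the 10 fits that left out 1 array. The quiescence list lay lower than other genes (camera adjusted p = 2.00e-05, exact permutation p of its array means 0.00794), with an adjusted p of 0.0661 with an estimated correlation.

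**Figure D2:**
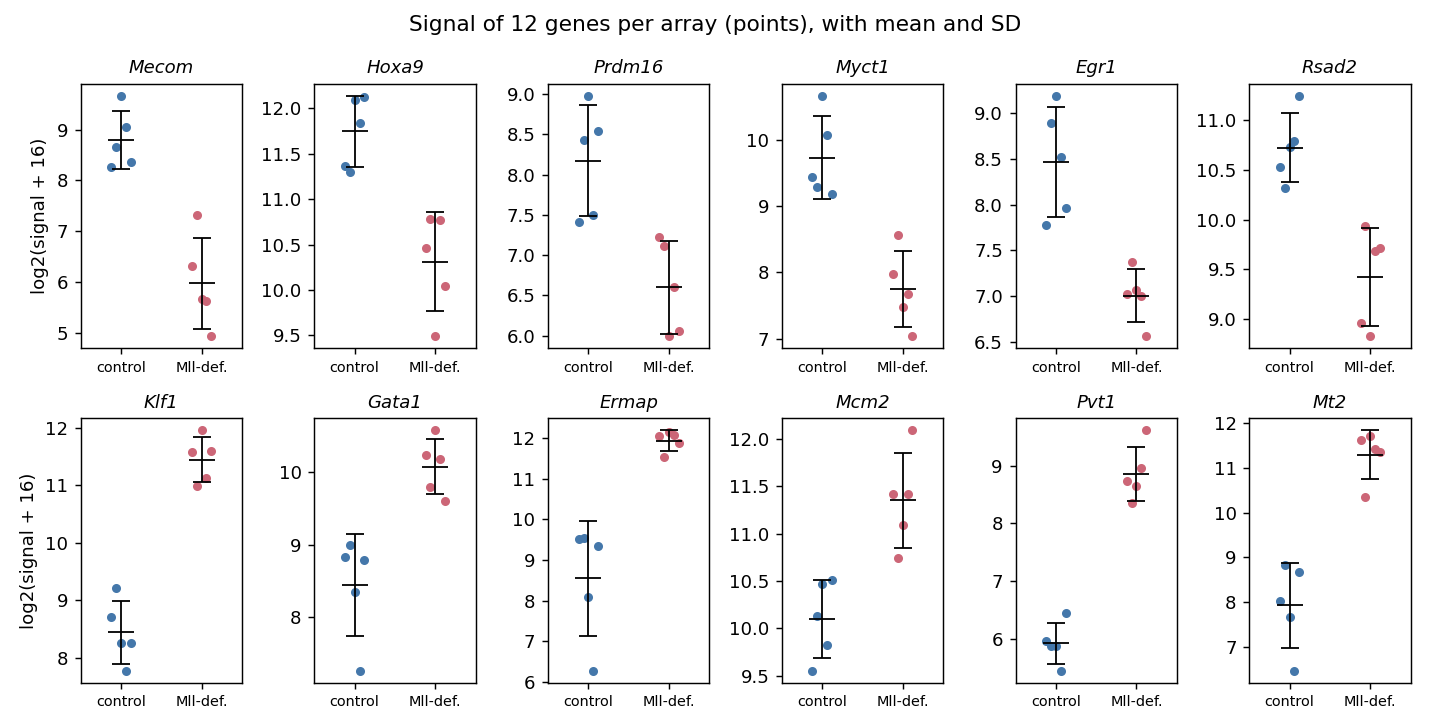
Points show log2(signal + 16) on each array for 12 genes in control (left of each panel) and Mll-deficient samples (right), with the mean and SD of 5 arrays and a separate y axis per gene. The groups did not overlap for any of the 12. Mecom signals lay between 14.5 and 144 in Mll-deficient samples and between 290 and 799 in controls.

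Erythroid genes were among the largest rises. Klf1, the transcription factor that activates globin and other erythroid genes, rose from 354 ± 145 to 2860 ± 774 (SD, n = 5 each), a log2 difference of 3.00 ± 0.27 (SE, adjusted p = 2.52e-05). The erythroid membrane protein genes Ermap and Aqp1 rose by 3.40 ± 0.48 (adjusted p = 7.93e-04) and 2.40 ± 0.42 (adjusted p = 0.00402), and Cldn13 rose by 3.16 ± 0.52 (adjusted p = 0.00241). Gata1, the master regulator of the lineage, rose from 362 ± 143 to 1098 ± 294, a difference of 1.63 ± 0.30 (adjusted p = 0.00589). Of 17 tested erythroid genes, 11 rose and 6 did not pass, and adjusted over the list alone 14 rose. All 17 had a difference above 0, with a median of 1.43. The list lay higher than other genes (camera adjusted p = 1.71e-15), with an adjusted p of 0.0521 with an estimated correlation. Its array means did not overlap between the groups (exact permutation p = 0.00794, the smallest possible, and 0.0261 adjusted). Of 4 probe sets shared by several globin genes, which name no single gene, 3 rose and 1 alpha globin probe set did not pass (0.80 ± 0.36, adjusted p = 0.240). The brightest alpha globin probe set read 226 ± 188 in controls and 1054 ± 642 in Mll-deficient samples (2.20 ± 0.43, adjusted p = 0.0110), and the beta globin one read 553 ± 153 and 1421 ± 359 (1.34 ± 0.23, adjusted p = 0.00505). A dimmer alpha globin probe set read 35.9 ± 26.4 in controls and 298 ± 156 in Mll-deficient samples (2.59 ± 0.36, adjusted p = 0.00103).

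Some genes of DNA replication, respiration and ribosomes rose as well. Mcm2, a subunit of the replicative helicase, rose by 1.26 ± 0.26 (adjusted p = 0.0116), Rfc4, a clamp loader subunit, by 1.31 ± 0.29 (adjusted p = 0.0141), Exo1, an exonuclease, by 0.94 ± 0.22 (adjusted p = 0.0225) and Rpa2, a subunit of the single-strand binding protein, by 0.85 ± 0.20 (adjusted p = 0.0206). Of 40 S phase genes, 9 rose and 31 did not pass, and adjusted over the list alone 12 rose (median 0.47, camera adjusted p = 9.16e-09, adjusted p = 0.0521 with an estimated correlation, exact permutation p 0.00794). Of 35 genes of G2 phase and mitosis, 0 passed, in limma or adjusted over the list alone, and the median was -0.02 (camera adjusted p = 0.599). Kif11 was nearest, at -0.63 ± 0.19 (adjusted p = 0.0650). Of 73 respiratory chain and ATP synthase genes, 10 rose and 63 did not pass, and adjusted over the list alone 27 rose (median 0.46, camera adjusted p = 5.80e-15, adjusted p = 0.112 with an estimated correlation). The largest rises were Atp5g1 and Atp5k, subunits of ATP synthase, at 1.71 ± 0.26 and 1.57 ± 0.27 (adjusted p = 0.00144 and 0.00328). Of 47 ribosomal protein genes, 6 rose and 41 did not pass, and adjusted over the list alone 12 rose (median 0.49, camera adjusted p = 1.88e-11, adjusted p = 0.148 with an estimated correlation). The leading members were Rpl41 (2.58 ± 0.46, adjusted p = 0.00451), Rpl22l1 (1.48 ± 0.29, adjusted p = 0.00801) and Rps27l (1.33 ± 0.25, adjusted p = 0.00654). The latter pair are paralogs of ribosomal protein genes, as is Rpl7l1, which rose by 0.85 ± 0.20 (adjusted p = 0.0236). The call of Rpl7l1 was lost in 4 of the 10 fits that left out 1 array. Another probe set of Rpl41 rose by 1.52 ± 0.31 (adjusted p = 0.0147), and a further pair, at -0.00 ± 0.23 and 0.12 ± 0.21, did not pass. The calls of Exo1 and Rpa2 were lost in 3 and 2 of the 10 fits that left out 1 array. The other probe set of Mcm2 was at 0.93 (adjusted p = 0.0523). The other probe sets of Rfc4 and Rpa2 had differences of -0.02 ± 0.28 and 0.08 ± 0.27 (adjusted p = 0.977 and 0.918), and averaging the probe sets ended the calls of Rpa2 (adjusted p = 0.136) and Exo1 (0.50, adjusted p = 0.0514).

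Both groups had received the interferon inducer, and 5 of 44 tested interferon-induced genes fell in Mll-deficient cells. Rsad2, an antiviral enzyme, fell from 1719 ± 437 to 703 ± 230 (SD, n = 5 each), a difference of -1.30 ± 0.25 (SE, adjusted p = 0.00749). The interferon-inducible GTPase genes Iigp1 and Gbp6 fell by 1.20 ± 0.27 (adjusted p = 0.0183) and 0.77 ± 0.19 (adjusted p = 0.0295), and Rtp4 fell by 0.95 ± 0.25 (adjusted p = 0.0334). The remaining 39 did not pass, and adjusted over the list alone 11 fell. The median was -0.47 (camera adjusted p = 2.85e-07, adjusted p = 0.156 with an estimated correlation). The exact permutation p of its array means was 0.0238 (0.0608 adjusted). The other probe set of Rtp4 was at -0.38 (adjusted p = 0.626), averaging the probe sets ended its call (adjusted p = 0.136), and the replicate block ended that of Gbp6 (adjusted p = 0.0702). The calls of Iigp1, Gbp6 and Rtp4 were lost in 4, 7 and 6 of the 10 fits that left out 1 array.

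**Figure D3:**
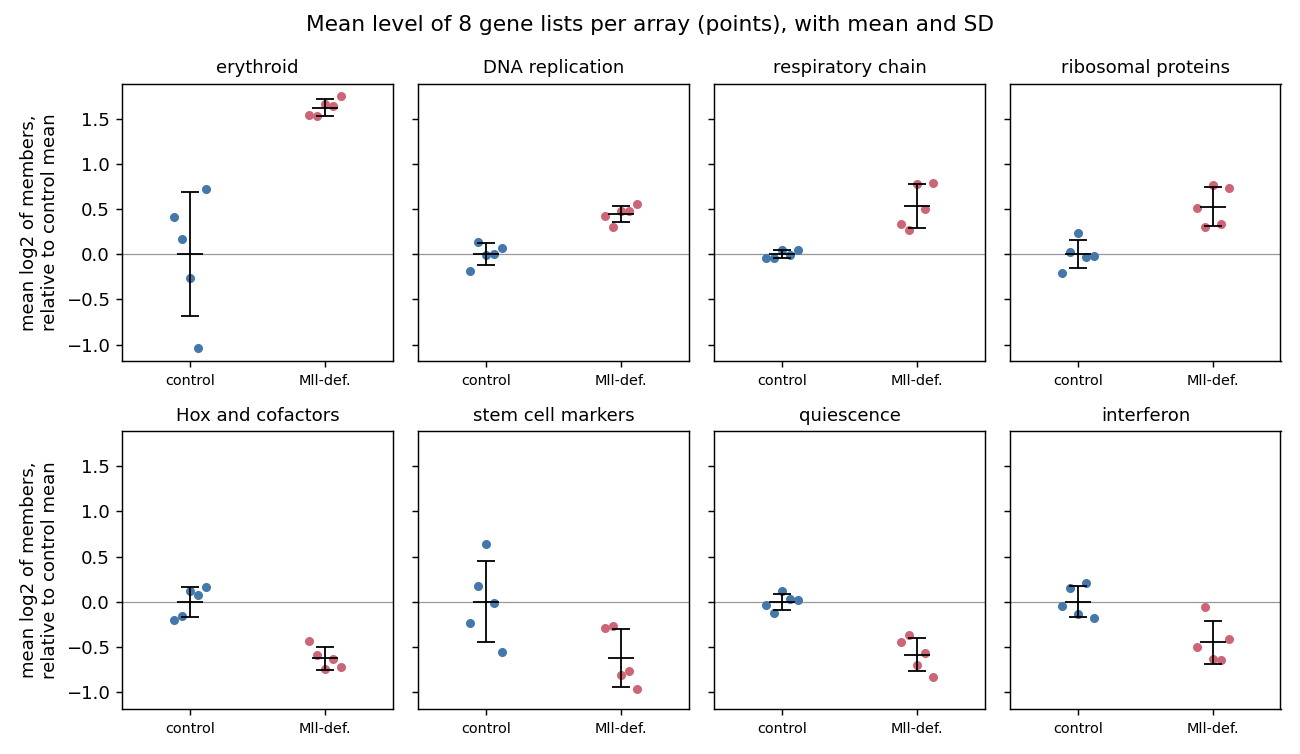
Points show the mean log2 value of the tested members of 8 gene lists on each array, relative to the mean of the controls, for control and Mll-deficient samples, with the mean and SD of 5 arrays. Erythroid means lay between 1.52 and 1.75 in Mll-deficient samples and between -1.04 and 0.73 in controls, while stem cell marker and interferon means overlapped.

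Markers of other cell types that the sorted fraction could hold were compared as well. Among 22 granulocyte and monocyte genes 0 passed in limma, adjusted over all genes or over the list alone (median -0.0030 and mean 0.0054, camera adjusted p = 0.773). Mpo, the myeloperoxidase gene, had a difference of 0.71 ± 0.33 (adjusted p = 0.240) and Mmp9, a neutrophil protease gene, of -1.03 ± 0.36 (adjusted p = 0.113). Among 15 genes of multipotent and lymphoid-primed progenitors, Il7r, the interleukin 7 receptor gene, fell by 1.37 ± 0.38 (adjusted p = 0.0443) and Tcf3, which encodes E2A, rose by 1.04 ± 0.23 (adjusted p = 0.0161), while 13 did not pass, among them Flt3 (-0.34 ± 0.23, adjusted p = 0.427) and Cd48 (0.25 ± 0.33, adjusted p = 0.722). Adjusted over the list alone 3 fell and 1 rose (camera adjusted p = 0.313), and the calls of Il7r and Zfpm1 were lost in 6 and 5 of the 10 fits that left out 1 array. Their other probe sets, at -0.47 and 0.86, did not pass (adjusted p = 0.492 and 0.0619). Averaging the probe sets ended the calls of Tcf3 (0.37, adjusted p = 0.222) and Il7r (-0.92, adjusted p = 0.133), and the latter also ended with offset 1, quantile normalization and no filter (adjusted p = 0.0581, 0.0652 and 0.0684). Of 18 megakaryocyte genes, 1 rose (Zfpm1, a cofactor of Gata1, 1.10 ± 0.27, adjusted p = 0.0277) and 17 did not pass, and adjusted over the list alone 1 rose and 1 fell. That list lay lower than other genes (median -0.40, camera adjusted p = 0.0213, adjusted p = 0.457 with an estimated correlation), and the call ended with the stricter filter and in 4 of the 10 fits that left out 1 array. Of 13 T and natural killer cell genes, 1 rose, Thy1, and 12 did not pass, and adjusted over the list alone 2 rose. Its median was 0.39 (camera adjusted p = 0.0213, adjusted p = 0.255 with an estimated correlation, lost in 3 of the 10 fits that left out 1 array).

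The B lineage, mast cell and basophil, and stroma and endothelium lists had 0 genes past the limma threshold, adjusted over all genes or over the list alone (camera adjusted p = 0.648, 0.966 and 0.191). Of 15 macrophage and dendritic cell genes, Vcam1, an adhesion molecule, fell by 0.81 ± 0.22 (adjusted p = 0.0441), as the only one also when adjusted over the list alone (camera adjusted p = 0.313), and this call was lost in 9 of the 10 fits that left out 1 array. The other probe set of Vcam1 was at -0.50 (adjusted p = 0.377), and its call also ended in 5 alternatives that kept all arrays (quantile normalization, median centring, no filter, averaged probe sets and the replicate block, adjusted p between 0.0547 and 0.0697). The complexes of Mll and of related methyltransferases, and the BCL2 family, also had 0 genes past either adjustment (camera adjusted p = 0.599 and 0.945). The BCL2 family list had a median of 0.0084 and a mean of -0.03. Of 19 p53 target genes, Trp53inp1 and Sesn1, both stress-induced, fell by 1.12 ± 0.24 (adjusted p = 0.0127) and 1.33 ± 0.33 (adjusted p = 0.0285), and 17 did not pass. Adjusted over the list alone 3 fell and 2 rose (camera adjusted p = 0.413). Of 20 immediate early and heat shock genes, Egr1 and Fos fell, the latter by 1.24 ± 0.32 (adjusted p = 0.0334), and Hsph1, a chaperone, rose by 1.27 ± 0.21 (adjusted p = 0.00241), with the same counts adjusted over the list alone (camera adjusted p = 0.313). The other probe sets of Trp53inp1 and Hsph1, at -0.79 and 0.74, did not pass (adjusted p = 0.165 and 0.112), and those of Sesn1 lay between -1.25 and -0.20, of which the former passed (adjusted p = 0.0343). The calls of Sesn1 and Fos were each lost in 6 of the 10 fits that left out 1 array.

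Several of the largest changes lay outside the lists. The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins, rose by 3.37 ± 0.38 (adjusted p = 2.89e-04) and 2.50 ± 0.33 (adjusted p = 6.58e-04). Pvt1, a noncoding RNA next to Myc, rose by 2.92 ± 0.26 (adjusted p = 2.52e-05), and Sphk1, a sphingosine kinase gene, by 3.00 ± 0.32 (adjusted p = 2.51e-04). Other probe sets of Pvt1 differed by 0.52 and 0.46 (adjusted p = 0.237 and 0.359), and that of Mt1 by 0.46 (adjusted p = 0.459). Add2, a membrane skeleton gene, Lmna, the lamin A/C gene, Hpn, a serine protease gene, and Blvrb, a biliverdin reductase gene, rose by 2.98, 2.78, 2.68 and 2.52. Other probe sets of Add2 differed by 1.42, 1.21 and 1.29, the last not past the threshold (adjusted p = 0.126), and those of Lmna by 2.29 (adjusted p = 0.00996) and 0.49 (adjusted p = 0.454). Besides Mecom, the genes 8430419K02Rik, Abtb2 and Zbtb20 fell, with differences of -2.38, -2.03 and -1.99 (adjusted p = 7.93e-04, 0.0132 and 0.0275), while another probe set of Abtb2 was at -0.41 (adjusted p = 0.645) and those of Zbtb20 lay between -1.09 and -0.09, most of them not past the threshold. Plin5, Csgalnact1, Dsp, Ceacam10 and Clec4a3 fell as well, with log2 differences of -1.57, -1.54, -1.53, -1.56 and -1.52 and adjusted p between 0.00241 and 0.0494. Other probe sets of Plin5, Csgalnact1 and Ceacam10, at -0.22, -0.56 and -0.94, did not pass (adjusted p = 0.686, 0.338 and 0.133). Of 61 other probe sets of the named genes that passed, 54 had the same direction and 18 of these passed. The calls of Ceacam10 and Clec4a3 were each lost in 8 of the 10 fits that left out 1 array, and those of Zbtb20 and Dsp in 3. With all arrays kept, the call of Clec4a3 ended in 7 alternatives (offset 1, quantile normalization, median centring, no filter, averaged probe sets, no trend and array weights, adjusted p between 0.0506 and 0.0970) and that of Ceacam10 in 4 (offset 1, no filter, averaged probe sets and no trend, adjusted p between 0.0570 and 0.0750), and averaging ended that of Dsp (-0.59, adjusted p = 0.0932).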

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

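The tests of the erythroid pattern against the other cell types and against globin were chosen only after the result was seen, and so was the covariate fit as an alternative. In 274 groups of 5 arrays, 9 had 1 array far from the others by Dixon's criterion, fewer than the 13.7 that chance gives.

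The signal of Kmt2a was 52.2 on Mll-deficient replicate 4, where the next lowest of its group was 211. Mt2 read 1297 on Mll-deficient replicate 2 (next 2605), Ceacam10 149 on Mll-deficient replicate 5 (next 811), Il7r 31.6 on Mll-deficient replicate 1 (next 122) and Cenpf 421 on Mll-deficient replicate 5 (next 580.3). Among controls, Abtb2 read 1980 on replicate 5 (next highest 658), Ebf1 58.3 on replicate 2 (next lowest 336) and Fos 304 on replicate 3 (next lowest 546). The mean correlation of control replicate 5 with its group was 0.926 (next lowest 0.952).

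Of 17 erythroid genes 11 rose in Mll-deficient cells, with a median log2 difference of 1.43 over the list. With the 3' to middle ratio as a covariate the median was 1.45 (camera adjusted p = 5.53e-14 at the preset correlation). Without the covariate, the list had a camera adjusted p of 0.0521 with an estimated correlation. The ratio was close in both groups (2.97 in controls and 3.16 in Mll-deficient samples), so the covariate could move the difference little. These values argue against RNA quality as the whole cause only as far as this ratio measures it. The erythroid array means rose by 1.66 relative to those of 6 other cell type lists (exact permutation p = 0.00794, the smallest possible). That comparison was chosen after the result was seen, so its p is a description. Mature cells of these lineages should be removed by the lineage-negative gate in both groups, which limits how far their markers could rise. The values show only that the mean of these lists did not rise as the erythroid mean did. They do not decide on a loss of stem cells and do not speak to other cell types. Late erythroid cells or their RNA stay open. The lineage-negative, Kit-positive sort should remove such cells, but mature neutrophil genes also read high, with S100a8 at percentiles 99.96 to 99.998 of the arrays' signals. The 2 globin probe sets brightest in controls, of 4, were higher by 1.77 and early erythroid genes by 1.83. The former minus the latter differed by -0.06 between the groups (-0.0569, exact permutation p = 0.841). The left-out alpha globin probe sets differed by 2.59 and 0.80, above and below the early erythroid genes. This comparison therefore depends on the probe sets chosen. A response to Mll loss also stays open, and cre carriage was confounded with it.

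Of 44 interferon-induced genes 5 fell in Mll-deficient cells, with a median of -0.47 over the list, whose array means overlapped (exact permutation p = 0.0238, and 0.0608 adjusted). With the covariate the median was -0.44 (camera adjusted p = 1.57e-06). Here too the ratio was close in both groups, so the fit speaks only to what that ratio measures. With any 1 array left out the median stayed between -0.58 and -0.39 (highest camera adjusted p = 1.55e-05), so no single array carried the fall of the median. These camera values use the preset correlation, and the adjusted p was 0.156 with an estimated correlation. An effect of the Mx1-cre transgene cannot be told apart from Mll loss, since 0 control arrays came from cre carriers.

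Chance was argued against for the count of genes, where 1 of 100 splits of the arrays, the real one, gave as many as 694 and the highest other gave 23. The same held for the 887 probe sets (1 of 100 splits, highest other 43). As 100 of 126 possible splits were drawn, 1 in 100 was the smallest share that could be seen. Chance was not excluded for the 12 lists past camera at the preset correlation: 15 of 100 splits gave as many, and the highest other gave 15.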

How the results depend on the processing

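The fit with the 3' to middle ratio as a covariate was chosen after seeing the data; the other alternatives were fixed before the data were examined. All of the 694 genes that were tested under an alternative kept their direction there. Between 523 and 925 genes passed with the other offsets, scalings, filters, probe set rule, variance priors and array weights, with 340 lower genes under array weights. The covariate gave 1610 genes, including all 694 (968 higher, 642 lower), and 2433 probe sets. An adjusted p of 0.10 gave 1187 (714 higher, 473 lower), and an unadjusted p of 0.05 with a 2-fold change gave 312 higher genes. With no filter 588 probe sets passed, among more tested. The estimated correlation left 0 lists. No pairing by replicate number was seen in the residual correlations (-0.228 to 0.277), and 1 of 5 Mll-deficient arrays matched its own number best. These values do not exclude a shared batch. Replicate 5 had the highest 3' to middle ratio in both groups (5.24 in controls and 3.87 in Mll-deficient samples). The replicate block gave 588 genes and 12 lists. The causes were not tested.

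Without 1 array, 317 to 875 genes passed (242 to 554 higher, 75 to 321 lower), as did 308 to 1129 probe sets and 10 to 12 lists. The share of higher genes was 68.2%, and 78.3% without control replicate 3. Of 60 named genes past the threshold, 42 passed in every alternative that kept all arrays and 32 in every alternative. Averaging all probe sets of a gene ended 16 of these calls, those of Meg3, Prdm16, Hoxb3, Hoxa10, Tcf3, Uqcrq, Eya1, Ceacam10, Dsp, Clec4a3, Il7r, Vcam1, Rtp4, Rpa2, Exo1 and Tob1 (adjusted p between 0.0514 and 0.473). The averages included probe sets below the filter. Hoxb3, Hoxa10, Tcf3, Dsp, Clec4a3, Exo1 and Tob1 had no other tested probe set, so their losses do not show tested probe sets in conflict. The difference of Clec4a3 stayed at -1.52 when averaged.

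Results that changed sign had not passed. With averaged probe sets the medians were 0.0682 for myeloid, 0.0092 for B lineage, -0.0566 for BCL2 family and -0.00247 for Mll and related complex genes, and Bcl2l1 was -0.0273. With the covariate they were 0.0197 for myeloid and 0.0238 for G2 and mitosis genes. The BCL2 family had -0.163 with an offset of 1 and -0.100 with the 60th percentile filter. Without 1 array, Kmt2a (1427283_at) ranged from -0.54 to 0.0221, and the medians from -0.0956 to 0.114 (myeloid), -0.190 to 0.127 (B lineage), -0.101 to 0.238 (mast cell and basophil), -0.309 to 0.0464 (macrophage and dendritic), -0.241 to 0.122 (G2 and mitosis), -0.235 to 0.00546 (p53 targets) and -0.116 to 0.0463 (BCL2 family). The cause was not tested. Signal near the floor of each array, 9.07 to 23.9, limits what dim genes can show.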

Other observations

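The gene lists for haem synthesis, ribosome biogenesis, and mitochondrial import and chaperones were chosen only after the data were seen, as were the members named here, so no test of these lists is given and their counts are descriptions. Of 8 tested genes of haem synthesis, 5 rose in Mll-deficient cells and 3 did not pass, with a median of 1.12. Alad, which joins aminolevulinic acid molecules, rose by 2.22 (adjusted p = 5.07e-04), Cpox, coproporphyrinogen oxidase, by 1.65 (adjusted p = 4.58e-04) and Fech, which inserts iron, by 1.57 (adjusted p = 0.00158). Alas2, the erythroid form of the first enzyme, differed by 0.73 (adjusted p = 0.389) and Alas1, its general form, by 0.16 (adjusted p = 0.791).

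Of 28 ribosome biogenesis genes, 13 rose and 15 did not pass, and all 28 differences lay above 0 (median 0.88). Nolc1, a nucleolar phosphoprotein, rose by 1.52 (adjusted p = 0.00186), Ddx21, a nucleolar helicase, by 1.27 (adjusted p = 7.37e-04) and Nop56, a small nucleolar ribonucleoprotein component, by 1.17 (adjusted p = 0.00241). Of 24 genes of mitochondrial import and of mitochondrial or cytosolic chaperones, 9 rose and 15 did not pass (median 0.68). The genes of the cytosolic chaperonin in this list were Tcp1, which rose by 0.89 (adjusted p = 0.0251), and Cct genes, which did not pass. Hspe1, a mitochondrial chaperonin, rose by 1.75 (adjusted p = 7.93e-04), Timm10, an import chaperone, by 1.59 (adjusted p = 0.00116) and Phb2, prohibitin 2, by 1.48 (adjusted p = 6.58e-04).

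Genes of mature neutrophils, a cell type that the lineage-negative gate would remove, were examined within the groups, with a list chosen after the data were seen whose 11 members all belong to the granulocyte and monocyte list. S100a8 read 23795 ± 8157 (SD, n = 5) in controls and 25895 ± 5032 (SD, n = 5) in Mll-deficient samples (0.16 ± 0.22, SE, adjusted p = 0.745), and Ngp 20237 and 21911 (adjusted p = 0.802). Within groups, the 11 genes had a mean pairwise correlation of 0.470, at percentile 97.04 of 10000 random lists of the same size matched on signal, whose median was 0.143. RNA of neutrophils carried into the sort is a candidate explanation of this co-variation, as is a program shared by the sorted cells, which was not tested.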
